A study of Danio rerio with 106 samples.

How the data were processed

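The deposited table holds counts of reads per gene for 106 single embryos, made by the authors with CASAVA 1.8, Bowtie2 2.1.0 against the Zv9 build and HTSeq 0.5.4p3, per the submitters' processing notes. The RNA was primed with barcoded oligo-dT and read at its 3′ end, and the embryos came from a spawning of several females with 1 male, per the labels' protocols. Each embryo stood on 2 entries of the sample sheet and in 1 column of counts. The table held 32433 gene IDs, 92 spike-in RNAs and 5 lines of unassigned reads, which were kept out of library totals. The median embryo had 23.64% of reads not aligned, 20.94% aligned outside annotated genes and 0.56% ambiguous. No molecular identifiers are mentioned in the notes, so floors and intervals cover counting error only. In the window comparisons the p values measure the spread between single embryos that differ in age and, in most windows, in library pool. No p value covers differences between spawnings.

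Gene reads per embryo had a median of 1394484, and 24 embryos lay under 697242, which is 0.5 of that median. A median of 8329 genes had a read. Of the gene IDs 20768 had a symbol, and 3172 shared their symbol with another, for which the ID is printed. The symbol was in capitals for 10375 gene IDs. Such symbols were taken as names of human orthologs, and they do not show which zebrafish copy of a gene was read. From 33 gene lists fixed before the data were examined, 732 of 844 members were matched. Members without a match by zebrafish symbol were matched by human symbol, a final a or b left off where needed. A member could hold up to 3 gene IDs. The windows, thresholds, gene lists, named-gene rule and most alternatives were likewise chosen before the data were examined.

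Adjacent windows were compared with edgeR 4.0.16 (filterByExpr with min.count 10, TMM scaling, robust quasi-likelihood F test), each in a fit of its own. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Counts of list members are out of those that passed the read filter, which a gene read in only the later window can pass. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with p adjusted over all 103 list tests, and again with an estimated correlation and with fry. Of these tests 51 passed, 37 up and 14 down. Of the 51 calls, 9 held with an estimated correlation, 40 with fry and 48 with RLE scaling, and 0 reversed direction. Levels in the window comparisons, those of the 320 min embryo beside them included, are CPM relative to the TMM-scaled library total, as mean and SD. Levels of single embryos in the figure and the closing sections, and those behind half-rise times, are CPM relative to the unscaled total of gene reads. Where a window had no read of a gene, the fold is a bound against a floor of 3 reads over that window, and genes with 1 to 3 reads in a window are given without a fold. With such genes held at their bound the median change of all genes was the same.

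Genes were named by a rule: up to 8 per direction with the largest fold among genes with a symbol, at least 20 CPM in the higher window and an area under the ROC curve of at least 0.95, and 2 members of each of the 5 lists with the smallest camera p. Other list members were named after their values had been seen. Change with time was tested in edgeR with a natural spline of 6 degrees of freedom on log2 minutes, and a rhythm with a 24 h harmonic beside a trend of 4 degrees of freedom. Half-rise times were taken from running medians over 5 embryos for genes with a maximum of at least 5 CPM. Correlations were tested with 100000 permutations. An embryo's age was matched by expression over 2000 genes with its own profile left out, after thinning to 141907 reads and leaving out 5 embryos under 100000 reads.

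The tests were tested on simulated data with 200 changed genes. Genes changed 16-fold were called in 22.7% of cases between cleavage and blastula, 28.8% between blastula and gastrula, 62.1% between gastrula and segmentation, 86.4% between segmentation and pharyngula and 90.9% between pharyngula and hatching, with 1, 5, 1, 3 and 0 false calls. Thinning was first done with edgeR's thinCounts and was replaced, after a first result was seen, by sampling without replacement: on simulated counts with a true share of 83.3%, thinCounts at 5000 of 120000 reads returned 29.7% and exact sampling 83.2%. The time test gave 1691 false calls among 14981 simulated genes and 2 among 8722 when only genes read in at least 53 embryos were kept.

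Alternatives covered scaling (RLE, and spike-in scaling added after the data were seen), filtering, DESeq2 1.42.0, limma-voom, 1 fit for all windows, window borders, shallow libraries, thinning, library pool, single embryos left out, spline and period. Embryos matched over 400 min from their label and libraries under 100000 reads were left out in alternatives added after the data were seen. R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. No genome sequence was used here, so near-identical gene copies could not be told apart.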

Results

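Polyadenylated RNA was measured in 106 single zebrafish embryos, 1 embryo every 40 min from 40 to 4240 min after fertilization, by CEL-Seq, an assay in which an embryo-specific barcode is added at the 3′ end of each transcript before the embryos are pooled, amplified and sequenced. No time point was repeated. Neighbouring embryos were therefore compared in 6 windows, named here after the textbook stage of their time range, since the labels give minutes only. The cleavage window held 4 embryos (40 to 160 min), the blastula window 3 (200 to 280 min), the gastrula window 8 (320 to 600 min), the segmentation window 20 (640 to 1400 min), the pharyngula window 36 (1440 to 2840 min) and the hatching window 35 (2880 to 4240 min). The border between the cleavage and blastula windows was set near the mid-blastula transition, not at the start of the blastula stage. These names are therefore approximate. The spread within a window includes the change with time inside it.

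Gene reads per embryo ranged from 17261 to 10217895, with a median of 1394484. The gastrula window was the shallowest, with a median of 255992.5 reads (range 141907 to 908481). The medians were 943506 reads (439353 to 1620208) in the cleavage window and 727866 reads (404297 to 1015423) in the blastula window. They were 980548 reads (20984 to 2279740) in the segmentation window, 1704519 reads (82562 to 4709802) in the pharyngula window and 1771105 reads (17261 to 10217895) in the hatching window. The embryos were sequenced in 2 library pools of 53 embryos each. Pool A held every cleavage and blastula embryo and 1 of 8 gastrula embryos, so that the change from blastula to gastrula largely coincided with a change of pool. The later windows drew on both pools, with 11, 18 and 16 embryos in pool A and 9, 18 and 19 in pool B.

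The time course was designed to follow when genes come on and go off through early development. Transcripts of oocyte and germ plasm genes were present from the start. The running median began at or above 50% of its maximum for 16 of 18 measured oocyte genes and 8 of 8 germ plasm genes. Its first value spans the embryos of 40 to 120 min. Several genes reached the maximum later, such as buc and WEE2 at 200 min and CCNA1 at 280 min. Lists of first zygotic genes and of mesendoderm genes followed, with median half-rise times of 360 min (interquartile range 320 to 420, 15 genes) and 440 min (360 to 520, 23 genes). The half-rise time is the first time at which the running median over 5 neighbouring embryos reached 50% of its maximum. Genes of somite formation had a median of 520 min (440 to 820, 20 genes), ribosomal protein genes 760 min (720 to 800, 69 genes), neural progenitor genes 780 min (620 to 1250, 24 genes) and epidermal genes 820 min (510 to 1970, 24 genes). Lists named after organs and their products came later, with 1520 min for cardiac (9 genes) and endothelial genes (11 genes). Liver plasma proteins had a median of 1760 min (20 genes), erythroid genes 1820 min (14 genes) and skeletal muscle genes 1960 min (31 genes). Single embryos were read without separating tissues, so a list's name does not show in which tissue its genes were expressed. The latest lists were lens proteins at 3080 min (2660 to 3560, 23 genes), neuronal genes at 3480 min (2140 to 3700, 23 genes) and photoreceptor genes at 3800 min (3160 to 3920, 13 genes). With 25% of the maximum in place of 50%, the median of 20 of 32 lists moved by over 120 min, for example that of neuronal genes to 2400 min and that of liver plasma proteins to 1120 min. These times are descriptions without a test. On simulated genes of 50 CPM, relative to the total of gene reads, they came out 200 min late at the median, with 53% within 200 min. Every simulated gene had the same spread between embryos, which was set beforehand and not estimated from these data. The simulated error is therefore not the error of the times given here.

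**Figure D1:**
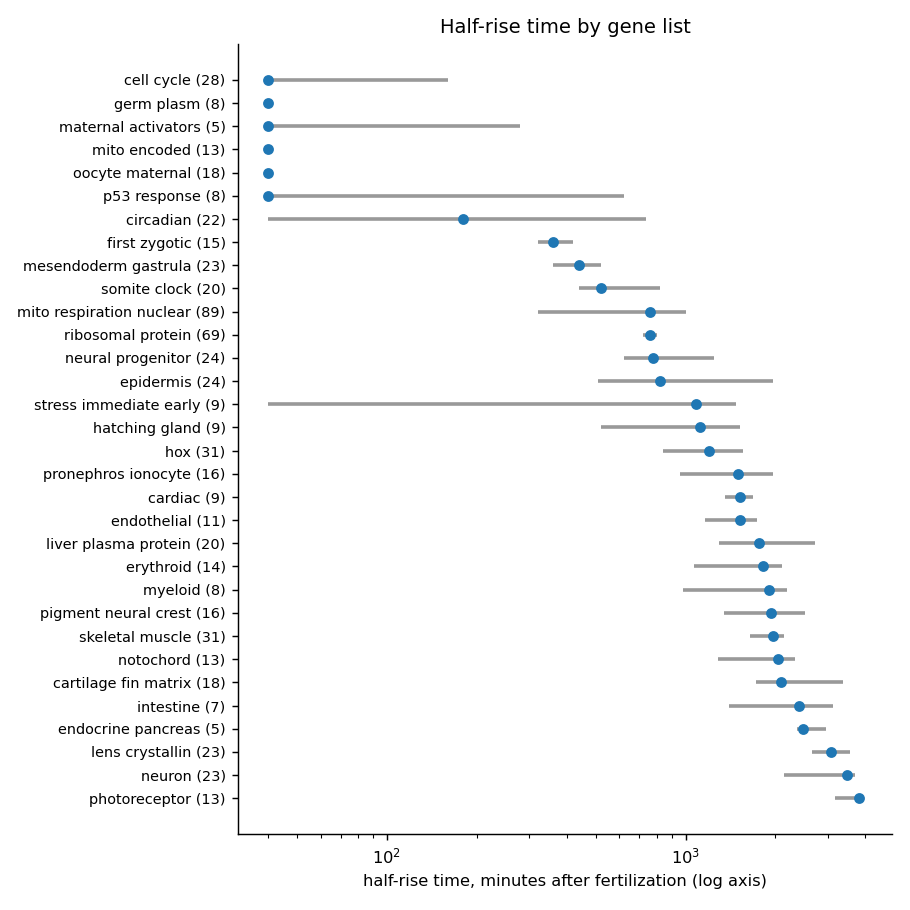
Median half-rise time of each gene list in minutes after fertilization, on a log axis; points are medians over the measured genes, whose number stands in brackets, and bars are interquartile ranges. First zygotic genes lie at 360 min, skeletal muscle genes at 1960 min and photoreceptor genes at 3800 min.

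The first comparison asked which transcripts changed between cleavage and blastula, when the embryo's own transcription is known to begin. No gene changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at an absolute log2 fold change of at least 1: 0 of 6626 genes were higher and 0 lower, and the smallest adjusted p was 0.534. Among oocyte genes, cldnd (ENSDARG00000006580) stood at 3720 ± 597 CPM (SD, n = 4) in the cleavage window and 1530 ± 165 CPM (n = 3) in the blastula window, with an adjusted p of 0.53 in edgeR. None of the 17 oocyte genes tested passed over all genes tested, and 3, cldnd, org and MOS, were lower adjusted over the list alone. The list was lower by limma's camera (adjusted p = 0.0339) but not with an estimated correlation between genes (adjusted p = 0.258). The 13 mitochondrially encoded genes were lower by camera (adjusted p = 0.00367), with an adjusted p of 0.606 with an estimated correlation, and 0 of them passed alone. An unadjusted edgeR p under 0.05 was reached by 242 genes, 64 higher and 178 lower, against 331.3 by chance. DESeq2 called 12 genes higher and 35 lower, limma-voom 4 and 3. On simulated data of these 7 embryos the test called 0% of genes changed 4-fold and 22.7% of genes changed 16-fold, so smaller changes were not detectable at this depth and number.

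Between the blastula and the gastrula, some genes of early patterning rose from no read and some maternal transcripts fell, while most members of the oocyte and germ plasm lists did not pass. The T-box gene tbx16 (ENSDARG00000007329), which acts in trunk mesoderm formation, had no read in 3 of 3 blastula embryos and 560 ± 250 CPM (SD, n = 8) in 8 of 8 gastrula embryos, at least 352-fold higher against a floor of 3 reads over the blastula embryos. The BMP antagonist chrd (ENSDARG00000006110) went from no read to 326 ± 243 CPM, at least 205-fold higher. The claudin gene cldne, at 152 ± 86.1 CPM, was at least 95.4-fold higher. In the other direction, slbp2 (ENSDARG00000069428), an oocyte form of the histone mRNA stem-loop binding protein, fell from 303 ± 160 CPM (n = 3) to no read in 8 of 8 gastrula embryos, at least 283-fold lower. SNX10, at 169 ± 61.3 CPM, and LSM1, at 169 ± 51.3 CPM in the blastula, also had no gastrula read, each at least 158-fold lower. Floors and bounds cover counting error only.

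Of 6135 genes, 224 changed by edgeR with Benjamini-Hochberg adjustment, 122 of them higher in the gastrula and the rest lower, and the named genes had adjusted p from 4.4e-13 (tbx16) to 0.05 (NDUFS6, under the threshold before rounding). The other genes of largest rise were SLC7A8, an amino acid transporter, at 444 ± 212 CPM (at least 280-fold), stm, which encodes an otolith matrix protein, at 427 ± 160 CPM (at least 269-fold), si:ch211-125o16.4 and ZIC2 (ENSDARG00000015554). The other genes of largest fall were pias4b, sybu, LPIN2, bcorl1 and SSH2, each without a gastrula read and at least 152-, 142-, 128-, 127- and 124-fold lower. Among mesendoderm genes 4 of 21 rose, tbx16, chrd, noto and FGF8 (ENSDARG00000003399), and 16 adjusted over the list alone. That list was the one of this comparison whose camera call (adjusted p = 6.07e-12) held with an estimated correlation (adjusted p = 0.0258). First zygotic genes rose in 3 of 14 members (7 over the list alone; camera adjusted p = 2.03e-07, and adjusted p = 0.0943 with an estimated correlation), among them cdx4, read in 6 of 8 gastrula embryos at 255 ± 287 CPM. Epidermal genes rose in 6 of 15 members (8 over the list alone; camera adjusted p = 9.78e-07, and adjusted p = 0.172 with an estimated correlation), among them krt8 from 31.8 to 2300 CPM and ANXA1 from 1 read to 311 ± 217 CPM. Somite genes rose in 2 of 12 members, HES6 (ENSDARG00000019335) and ALDH1A2 (11 over the list alone; camera adjusted p = 3.28e-05, and adjusted p = 0.291 with an estimated correlation).

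Oocyte genes fell in 5 of 17 members, slbp2, buc, cth1, BTG4 and WEE2 (7 over the list alone; camera adjusted p = 3.94e-05, and adjusted p = 0.21 with an estimated correlation). The egg gene buc, which organizes the germ plasm, fell from 749 to 30.8 CPM and WEE2, an oocyte kinase, from 1100 to 86.8 CPM. Ribosomal protein genes rose in 4 of 69 members, with RPL27 at 536 ± 502 CPM in the blastula and 2030 ± 700 CPM in the gastrula (camera adjusted p = 1.81e-12, and adjusted p = 0.422 with an estimated correlation). The count of such genes was 0 without the embryo of 200 min, 0 without that of 240 min, 11 without that of 280 min and 0 with the pool as a term. Of 28 cell cycle genes tested 2 rose and 4 fell, while 22 did not pass (camera adjusted p = 0.311). CCNB1 fell from 2680 to 633 CPM, while PCNA rose from 2730 to 7010 CPM. Higher genes made up 54.5% of calls with TMM scaling, 47.5% with RLE and 69.3% with spike-in scaling, and the median log2 change of all genes was -0.33, -0.51 and 0.02.

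With the library pool as a term, 7 genes were higher and 13 lower, all 7 of the former and 0 of the latter among the genes called without it. Of the 22 named genes 4 kept direction and call with the pool term, 16 lost the call and 2 (RPS13 and ANXA1) reversed direction. Pool A held 1 gastrula embryo (320 min), which was part of the comparison and is no independent check of the pool. In that embryo tbx16 stood at 216 CPM and chrd at 96 CPM. There was no read of slbp2, and cdx4, ANXA1, HES6 (ENSDARG00000019335) and ALDH1A2 had none either. Without the embryo of 200 min the counts were 61 higher and 31 lower, and without that of 240 min 50 lower. Without shallow libraries (under 697242 reads) 1 gastrula embryo remained and the counts were 0 and 0.

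Between the gastrula and the segmentation period every ribosomal protein gene tested rose with TMM scaling. Part of the genes on the lists of liver plasma proteins, notochord, hox, epidermis and neural progenitors also rose. Some did so from a level already present in the gastrula and others from no gastrula read. All 69 ribosomal protein genes were higher, among them RPL23A (ENSDARG00000006316) from 151 ± 119 CPM (SD, n = 8) to 1010 ± 353 CPM (n = 20). The protease inhibitor gene serpina1 (ENSDARG00000090286) went from 4 reads in 1 gastrula embryo to 240 ± 147 CPM in 19 of 20 segmentation embryos. The fatty acid transporter gene slc27a2a (ENSDARG00000036237) had no gastrula read and 169 ± 112 CPM, at least 192-fold higher against the floor of 3 reads, and the nuclear receptor gene nr2f5 124 ± 73.5 CPM, at least 141-fold higher. The pluripotency factor gene pou5f3 (ENSDARG00000044774) fell 14.3-fold, from 661 ± 215 to 45.4 ± 112 CPM, and nnr 14-fold, from 784 ± 300 to 55.3 ± 94.9 CPM.

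In this comparison 947 of 7058 genes were higher and 140 lower by edgeR with Benjamini-Hochberg adjustment, with adjusted p of 2e-12 for serpina1, 1.1e-11 for slc27a2a, 0.014 for pou5f3 and 0.013 for nnr. The other genes of largest rise were SRGAP2B, MPC1 and maptb, each without a gastrula read, and the muscle genes TNNI2 (ENSDARG00000035958), from 2.02 ± 5.73 to 193 ± 253 CPM, and myl10, from 7.79 ± 19.9 to 440 ± 352 CPM. The other genes of largest fall were PPT2, si:dkeyp-114g9.1, drll.3, znf1065, alox5b.3 and TENT5C, with falls from 9.86-fold (TENT5C) to 34.2-fold (PPT2). Liver plasma protein genes rose in 11 of 17 members (13 over the list alone), among them apoa1a from 394 to 3930 CPM and the complement gene c3a.1, which had no gastrula read and 35.3 ± 37.2 CPM, while HNF4A fell from 188 to 40.8 CPM, a fall not called with spike-in scaling (camera adjusted p = 1.21e-07, and adjusted p = 0.098 with an estimated correlation). Hox genes rose in 10 of 15 members (12 over the list alone), with HOXB9 at 70.8 ± 48.7 CPM and hoxa10b at 36.2 ± 30.4 CPM after no gastrula read (camera adjusted p = 3.13e-05, and adjusted p = 0.142 with an estimated correlation). All 5 notochord genes tested, of 18 on the list, rose (camera adjusted p = 0.00509, and adjusted p = 0.206 with an estimated correlation). COL9A2 went from 2.05 to 76.6 CPM and SHH (ENSDARG00000068567) from no read to 45 CPM.

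Epidermal genes rose in 10 of 19 members, for example krt4 from 1120 to 4250 CPM (camera adjusted p = 0.00325, and adjusted p = 0.393 with an estimated correlation). Neural progenitor genes rose in 9 of 18 members, among them the glial gene GFAP, from no read to 155 CPM, while ZIC2 (ENSDARG00000037178) fell from 478 to 176 CPM, which was not called with spike-in scaling (camera adjusted p = 0.00973, and adjusted p = 0.339 with an estimated correlation). Nuclear genes of mitochondrial respiration rose in 24 of 78 members, with NDUFS7 from 3.43 ± 9.69 to 58.3 ± 44.6 CPM and ndufa7 from 2.49 ± 7.05 to 55.6 ± 45.6 CPM (camera adjusted p = 2.15e-06, and adjusted p = 0.422 with an estimated correlation). Oocyte genes fell in 4 of 6 members (4 over the list alone): CCNA1 from 183 ± 181 to 1.8 ± 5.59 CPM, gdf3 from 138 ± 112 to 10.6 ± 15.2 CPM, tdgf1 from 407 to 54.1 CPM and org from 90.5 to 7.26 CPM. That list was the one whose camera call (adjusted p = 4e-08) held with an estimated correlation (adjusted p = 0.0148).

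The ribosomal protein list had a camera adjusted p of 1.4e-17 and an adjusted p of 0.291 with an estimated correlation. Its median log2 fold change was 1.97 with TMM, 0.78 with RLE and 2.57 with spike-in scaling, where all genes had medians of 0.50, -0.77 and 1.03. Higher genes made up 87.1% of calls with TMM, 29.1% with RLE and 95.8% with spike-in scaling. With RLE scaling, which rested on the 265 genes with a read in every embryo, 9 of the 69 ribosomal protein genes passed. Without shallow libraries 1 gastrula embryo remained and 73 genes were higher and 39 lower.

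**Figure D2:**
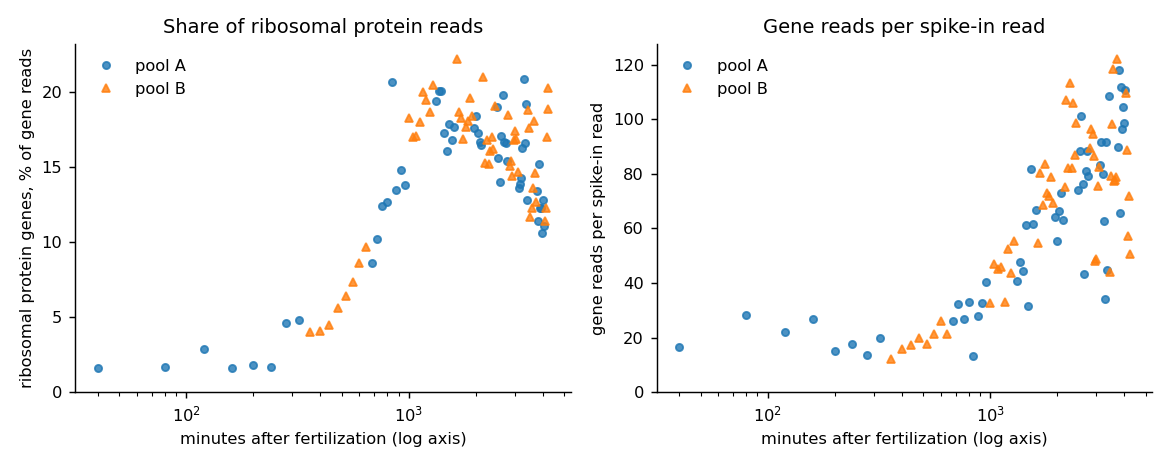
Each point is 1 embryo against minutes after fertilization on a log axis, by library pool: at left the percent of gene reads from ribosomal protein genes, at right the gene reads per spike-in read. The ribosomal share averaged 5.67% in the 8 gastrula embryos and 16.3% in the 20 segmentation embryos.

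Between the segmentation and the pharyngula period nearly all tested genes of the skeletal muscle list and every tested gene of the cartilage and fin matrix list rose. Of 30 skeletal muscle genes 29 rose (30 over the list alone), among them the fast myosin heavy chain gene myhz1.1 (ENSDARG00000067990) 44.7-fold, from 35.8 ± 36 CPM (SD, n = 20) to 1660 ± 864 CPM (n = 36), and MYOM2, a gene of the sarcomere M band, 57.3-fold, from 8.32 ± 12.6 to 496 ± 280 CPM. All 10 cartilage and fin matrix genes tested, of 24 on the list, rose. The collagen gene COL1A1 (ENSDARG00000035809) was 22.8-fold higher, from 38.7 ± 37 to 912 ± 464 CPM. The transglutaminase gene TGM2 (ENSDARG00000070157) had no segmentation read and 43.7 ± 33.8 CPM in the pharyngula, at least 349-fold higher. The caudal-type homeobox gene cdx4 fell 40.7-fold, from 208 ± 157 to 5.21 ± 12 CPM, and the keratin gene krt18a.1 3.48-fold, from 2120 ± 845 to 611 ± 202 CPM.

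In all, 1011 of 8508 genes were higher and 200 lower by edgeR with Benjamini-Hochberg adjustment, with adjusted p of 5.1e-16 for myhz1.1, 8.4e-12 for MYOM2, 2.9e-11 for COL1A1, 4.8e-15 for TGM2, 2.5e-08 for cdx4 and 9.2e-18 for krt18a.1. The other genes of largest rise were myoz1b, HHATL (ENSDARG00000039051), aep1, NPAS1 and TNNT3 (ENSDARG00000030270), with rises from 46.2-fold (TNNT3) to 93.7-fold (myoz1b). The other genes of largest fall were ctss2.1, SALL4 and UTP15, 4.30-, 3.90- and 3.02-fold lower, the last of which was not called with spike-in scaling. Camera calls that held with an estimated correlation were those for skeletal muscle (adjusted p = 9.75e-47, and 0.000454 with an estimated correlation), neurons (8.99e-15, and 0.00951), cartilage and fin matrix (2.39e-14, and 0.00951), erythroid genes (4.08e-07, and 0.0374), mesendoderm (2.12e-10, and 0.0177) and first zygotic genes (1.21e-07, and 0.045). Neuronal genes rose in 18 of 19 members, among them the GABA synthesis gene GAD2 and SNAP25 (ENSDARG00000058117), a gene of synaptic vesicle fusion, at 12.6 ± 13.5 and 14.5 ± 17.7 CPM after no segmentation read. Erythroid genes rose in 8 of 12 members, including the globin gene hbae3 from 238 to 3500 CPM, whose near-identical copies make the value of a single globin gene uncertain.

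All 17 lens genes tested, of 26 on the list, rose (17 over the list alone). The list had a camera adjusted p of 2.7e-16 and an adjusted p of 0.0659 with an estimated correlation. CRYBA4 went from no read to 16 ± 19.1 CPM, and the water channel gene MIP (ENSDARG00000037285) from 0.276 ± 1.15 to 50.9 ± 40.1 CPM. Pigment and neural crest genes rose in 8 of 13 members, with the melanin synthesis gene DCT from 3.12 to 49.6 CPM (camera adjusted p = 7.95e-07, and adjusted p = 0.0659 with an estimated correlation). Mesendoderm genes fell in 7 of 16 members (8 over the list alone), with chrd 49.8-fold lower, from 86.2 ± 110 to 1.59 ± 3.53 CPM, and msgn1, a gene of the unsegmented mesoderm, 21.1-fold lower, from 37.4 ± 46.2 to 1.64 ± 4.57 CPM. First zygotic genes fell in 5 of 13 members with TMM, and with spike-in scaling in 4, with 1 higher. Higher genes made up 83.5% of calls with TMM, 47.7% with RLE and 97.5% with spike-in scaling, and the median log2 change of all genes was 0.22, -0.25 and 0.91.

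Between the pharyngula and the hatching period, 12 of 19 lens and 13 of 21 neuronal genes rose further and 4 of 9 genes of the hatching gland fell. Of 19 lens genes 12 rose (13 over the list alone); the gamma-crystallin gene crygm2d21 (ENSDARG00000086658) rose 7.99-fold, from 81.4 ± 112 CPM (SD, n = 36) to 651 ± 396 CPM (n = 35). The copies of the crygm2d family, of which crygm2d7, crygm2d5, crygm2d17 and crygm2d2 were also named by the rule, are nearly alike, so the share of each copy is uncertain. Neuronal genes rose in 13 of 21 members (15 over the list alone), with the synaptic vesicle gene SYT1 4.12-fold higher, from 11.2 ± 10.7 to 45.7 ± 43.3 CPM. The hatching enzyme gene he1.3 (ENSDARG00000022670) fell 39-fold, from 68.5 ± 76.7 to 1.45 ± 3.94 CPM, and the hatching gland gene ctslb 3.89-fold, from 948 ± 355 to 245 ± 276 CPM. The troponin gene TNNI2 (ENSDARG00000035958) fell 4.59-fold, from 500 ± 184 to 107 ± 68 CPM.

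Of 8276 genes, 315 were higher and 142 lower by edgeR with Benjamini-Hochberg adjustment, with adjusted p of 7e-08 for crygm2d21, 0.00082 for SYT1, 3.5e-08 for he1.3, 1e-07 for ctslb and 4.3e-14 for TNNI2. The lens list was the one whose camera call (adjusted p = 1.11e-20) held with an estimated correlation (adjusted p = 0.045), while that of neuronal genes (adjusted p = 1.63e-11) had an adjusted p of 0.098 with it. Liver plasma protein genes rose in 2 of 19 members, the apolipoprotein gene apoa2 from 1660 ± 744 to 3790 ± 1730 CPM and CP, not called with spike-in scaling, from 43.9 ± 34.7 to 87.4 ± 72.6 CPM (camera adjusted p = 0.000215, and adjusted p = 0.388 with an estimated correlation). Hatching gland genes fell in 4 of 9 members, he1.1, he1.2, he1.3 and ctslb (camera adjusted p = 0.000336, and adjusted p = 0.142 with an estimated correlation). Cell cycle genes fell in 2 of 25 members, the replication licensing genes MCM4, from 160 ± 70.8 to 76.9 ± 50.9 CPM and not called with spike-in scaling, and MCM3, 2-fold lower (camera adjusted p = 4.78e-08, and adjusted p = 0.21 with an estimated correlation). Of 30 skeletal muscle genes 4 rose, among them pvalb2, and 3 fell with TMM, while 5 rose and 1 fell with spike-in scaling. Among those that fell with TMM was actc1a, from 1340 ± 367 to 537 ± 198 CPM, a gene nearly identical to actc1c, so that reads of the 2 cannot be assigned with certainty. Higher genes made up 68.9% of calls with TMM, 80.6% with RLE and 80.8% with spike-in scaling, and the median log2 change of all genes was -0.08, 0.06 and 0.05.

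**Figure D3:**
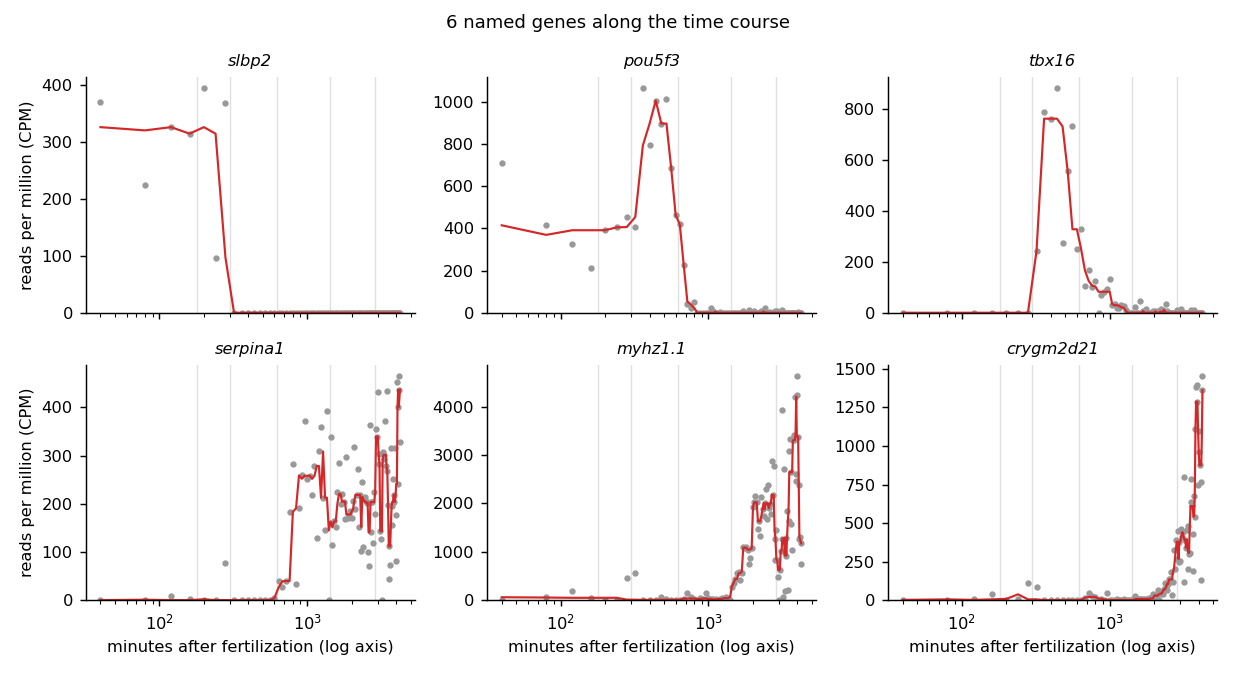
Level in CPM of 6 named genes in each of the 106 embryos (points) with the running median over 5 embryos (line), against minutes after fertilization on a log axis; grey lines mark the window borders. slbp2 had no read in the gastrula window, where tbx16 averaged 560 CPM with TMM scaling, and myhz1.1 rose between the segmentation and pharyngula windows.

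The time course as a whole was tested with a smooth curve of log2 minutes in edgeR over all 106 embryos. Of genes with a read in at least 53 embryos, 3752 of 7621 (49.2%) changed with time at an adjusted p under 0.05 (Benjamini-Hochberg), a gene set chosen after the first result was seen. Over all 14981 genes that passed the filter fixed before, 9022 (60.2%) did, but embryos in random order gave a median of 2078.5 such calls there, against 18 among the genes read in at least 53 embryos, so that the test called too many weakly expressed genes. Among the 3752 genes the fitted curve had its maximum in the cleavage window for 657 genes (17.5%), in the segmentation window for 683 (18.2%), in the pharyngula window for 838 (22.3%) and in the hatching window for 1230 (32.8%). The blastula and gastrula windows held 118 and 226 maxima. The minimum lay in the cleavage window for 2280 genes (60.8%). Genes read only up to the segmentation window could not enter this set, since those windows together hold fewer than 53 embryos. Genes read only in the later windows could, so these shares depend on the filter.

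Hox genes, which pattern the body axis, are known to come on in the order of their position in the clusters. The earliest by half-rise time were hoxb1b (ENSDARG00000054033) at 560 min, HOXB7 at 680 min and HOXB9 and HOXC6 at 720 min each. The latest were hoxb6b at 2760 min, HOXC5 at 2840 min and hoxa13b (ENSDARG00000036254) at 3080 min, the last of which peaked at a running median of 7.75 CPM. Across 31 hox genes the paralog group number was not related to the half-rise time beyond chance (Spearman rho = 0.28, permutation p = 0.127; Pearson r = 0.218, permutation p = 0.237; two-sided, r = 0.127 without the 2 genes farthest from the median). Genes are not independent replicates. On simulated genes of 50 CPM only 53% of half-rise times lay within 200 min, and many hox genes peaked below 50 CPM. The spread in that simulation was not estimated from these data, so the error of the hox times is not known. An order finer than that error could be missed. With half-rise replaced by the time at which 25% of the maximum was reached, rho was 0.429 (permutation p = 0.0172, range over the alternatives 0.0172 to 0.686).

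A rhythm of 24 h was sought in the 71 embryos from 1440 to 4240 min. The hatching enzyme genes he1.2 and he1.1 had fitted peak-to-trough ratios of 39.4 and 14.2, and 2 afp4 genes (ENSDARG00000041490 and ENSDARG00000095863), which bear the name of antifreeze proteins, ratios of 14.3 and 5.91. The muscle calcium pump gene atp2a1 had a ratio of 4.34. The size of these values rests in part on the trend of 4 degrees of freedom. With 3, the log2 amplitude of he1.2 was 0.85 in place of 2.65 (edgeR adjusted p = 0.107). That of he1.1 was 0.76 in place of 1.92 (adjusted p = 0.101), and afp4 (ENSDARG00000041490) lost its call too (adjusted p = 0.102). With 3, atp2a1 at 0.75 in place of 1.06 (adjusted p = 0.00651) and afp4 (ENSDARG00000095863) at 0.62 in place of 1.28 (adjusted p = 0.0371) still passed. Scaling and depth moved the calls too. With spike-in scaling he1.2, he1.1 and both afp4 genes lost their call (edgeR adjusted p = 0.128, 0.294, 0.0807 and 0.19), while atp2a1 kept it. Without shallow libraries atp2a1 and both afp4 genes lost it (edgeR adjusted p = 0.097, 0.622 and 0.0696), while he1.2 and he1.1 kept it. In edgeR 8 of 8276 genes passed an adjusted p of 0.05 (Benjamini-Hochberg), 6 of them with a symbol and at least 20 CPM, while 608 had an unadjusted p under 0.05 against 413.8 by chance. The sixth, SNAP25 (ENSDARG00000058117), was read in 53 of 71 embryos and its fitted ratio has no usable meaning. None of 11 circadian genes tested, of 33 on the list, passed in edgeR, over all genes or adjusted over the list alone. None had an unadjusted edgeR p under 0.05, and the smallest, 0.093, was that of nfil3-5. On simulated data the rhythm test called 26% of genes with a 4-fold peak-to-trough ratio and 73% with a 16-fold one. It could thus miss smaller rhythms of circadian genes. No call remained with a trend of 6 degrees of freedom in place of 4. There the amplitudes of the 6 named genes were 0.648 to 1.58 times those before (median 0.937), and the standard error of the 24 h terms was 3.12 times as large. Fitted peaks moved, that of atp2a1 from 20.58 to 5.06 h and that of he1.1 from 10.02 to 14.08 h. A period of 16 h gave 9 calls, 0 of them shared. Periods of 20 and 28 h gave 4 and 6 calls, with 4 and 5 shared. The light regime is not given in the sources used here.

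Neighbouring embryos were compared by their dissimilarity, 1 minus the Spearman correlation of their counts after thinning every embryo to 17261 reads. It was higher in later pairs across 53 non-overlapping pairs (Spearman rho = 0.617, permutation p = 2e-05; Pearson r = 0.355, permutation p = 0.011; r = 0.356 without the 2 pairs farthest from the median). Within pool A rho was 0.6 (23 pairs) and within pool B 0.769 (23 pairs). Median dissimilarity was 0.462 in the gastrula window (3 pairs), 0.458 in the segmentation window (9 pairs) and 0.508 in the hatching window (17 pairs). The relation depended on thinning: with counts as deposited rho was -0.085 (permutation p = 0.547, range over the alternatives 1e-05 to 0.547). Depth also remained in the thinned values: dissimilarity ran against the smaller total of the pair (Pearson r = -0.758, Spearman rho = -0.313), and the 5 pairs with a library under 100000 reads had the highest values, 0.598 to 0.709. Without pairs holding a shallow library rho was 0.777 (34 pairs). How evenly reads spread over genes also bears on this measure, and that changed with time. The 10 genes with most reads held a median of 36.52% of gene reads in the cleavage window and 26% in the gastrula window. They held 14.93% in the segmentation window and 14.13% in the hatching window. A faster change in later embryos can therefore not be read from the dissimilarity.

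Gene reads per read of the ERCC spike-in RNA, which the files list beside the genes, averaged 23.4 ± 5.28 in the cleavage window (SD, n = 4), 15.4 ± 2.06 in the blastula window (n = 3) and 18.7 ± 4.07 in the gastrula window (n = 8). They averaged 37 ± 10.9 in the segmentation window (n = 20) and 83 ± 23.6 in the hatching window (n = 35). Across the 106 embryos its log2 ran with log2 minutes (Pearson r = 0.828, Spearman rho = 0.767; permutation p = 1e-05 for each, the smallest that 100000 resamples can give; Benjamini-Hochberg adjusted p = 1.33e-05 and 1.14e-05 over 8 relations; r = 0.853 without the 2 farthest embryos). The relation held within pool A (r = 0.831, rho = 0.864) and within pool B (r = 0.859, rho = 0.652). The share of reads from 13 mitochondrially encoded genes averaged 3.25% ± 1.05 in the cleavage window, 1.97% ± 0.476 in the gastrula window and 3.25% ± 0.555 in the hatching window. It ran with time (r = 0.402, permutation p = 6e-05, adjusted 6.86e-05; rho = 0.58, permutation p = 1e-05, adjusted 1.14e-05; r = 0.433 without the 2 farthest embryos). In pool B r was 0.661 and rho 0.623, and in pool A rho was 0.51 while r was 0.225 (permutation p = 0.104).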

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

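Several tests named in this part were written after the result was seen. They were the share of ribosomal protein reads after thinning, the second thinning and the list's own change under 3 scalings. Further ones were both rhythm tests (16 h period and 6 degrees of freedom) and the split test of cleavage against blastula. The shuffles of age gaps and the gene number required for the first thinning were not part of the criteria written before.

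Of 55 groups of 4 to 10 values, 8 held an embryo far from the others by Dixon's criterion. The 2.8 expected by chance hold for normally distributed values only. Most groups were levels of named genes, and where a single embryo had reads the gap over range is 1 by construction. The count of 8 is therefore no sign of more outliers than chance gives. The gastrula embryos also differ in age. In the cleavage window the ribosomal protein share of the 120 min embryo was 2.89%, against 1.67% for the next (gap over range 0.961). The CPM in this paragraph are relative to the unscaled total of gene reads. In the gastrula window the 600 min embryo, the oldest, alone held reads of serpina1 (4.403 CPM, ratio 1), TNNI2 (ENSDARG00000035958) (14.31 CPM, ratio 1), ndufa7 (17.61 CPM, ratio 1) and NDUFS7 (24.22 CPM, ratio 1). The 400 min embryo was highest for myl10 (65.42 against 4.871 CPM, ratio 0.926), the 560 min embryo for si:dkeyp-114g9.1 (296 against 121.4 CPM, ratio 0.664) and the 320 min embryo for drll.3 (683.4 against 326.3 CPM, ratio 0.555). Outside the gene counts, a median of 20.94% of reads aligned outside annotated genes, a signal that the comparisons did not use.

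Other groupings of the embryos were run through the same tests. Between cleavage and blastula, 35 of 35 splits called at least as many genes as the real one (0), up to 2. With 0 real calls that outcome was fixed in advance and decides nothing. For blastula against gastrula 1 of 100 splits, the real one, reached 224 calls, where the highest other gave 80. For gastrula against segmentation it was 1 of 100 (1087 calls, highest other 77), for segmentation against pharyngula 1 of 40 (1211, highest other 0) and for pharyngula against hatching 1 of 40 (457, highest other 0). Among random orders, 1 of 21 reached 9022 genes changing with time (highest other 2414) and 1 of 21 reached 8 rhythm genes (highest other 0). A random order also removes slow change, so it cannot tell a 24 h rhythm from slow change.

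The rise of ribosomal protein genes from gastrula to segmentation may stem from shallow gastrula libraries, from scaling or from the library pool. With every embryo thinned to 20984 reads, 32.4% of the genes kept a fitted log2 change above 1, which met the criterion written for depth as the cause, but only 358 genes then entered the scaling, so that this test decides nothing. With the embryos of at least 100000 reads thinned to 141907 reads, 100% of the 69 genes kept it (8 gastrula and 19 segmentation embryos). At equal depth the rise thus remained, so it did not hinge on unequal totals in the read filter or the scaling. Random thinning leaves a gene's share of reads unchanged on average. The second thinning therefore cannot decide on any other bias of the shallow gastrula libraries. The share of ribosomal protein reads after the first thinning, 5.74 ± 1.77% in the gastrula and 16.27 ± 3.96% in the segmentation window, decides nothing because random thinning leaves a share unchanged on average. Within pool B 98.4% of the change was kept, which speaks against the pool. Scaling stays open for the size of the rise: the list's smallest median log2 change was 0.78 (RLE), and its excess over all genes, at least 1.47, cannot decide because a scaling shifts both alike. No biological explanation was tested.

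The age matched from expression lay a median of 40 min from the label, and over 400 min from it in 7 embryos, which could reflect low depth, the pool or exchanged labels. The gap did not fall with read count (rho = 0.24, permutation p = 0.0161, the other sign). This excludes nothing, because every embryo was thinned to 141907 reads before its age was matched, and 2 of the 5 largest gaps, at 3440 and 4200 min, were in libraries of 591653 and 554087 reads, under 0.5 of the median. Depth therefore stays undecided. The pools' mean gaps differed by 82.1 min (permutation p = 0.192), which leaves pool undecided. All 5 of the embryos with the largest gaps had a partner, which met the criterion for exchanged labels, but shuffled gaps gave as many one-to-one pairs (2) in 0.142 of draws, so this is undecided too. No biological explanation was tested.

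The 24 h rhythm calls may be slow change that the trend did not take up. A period of 16 h called 9 genes against 8, none of them shared, and that count met the criterion written for this cause. Periods of 20 and 28 h gave 4 and 6 calls, 4 and 5 of them shared, so part of the calls were not particular to 24 h. A trend of 6 degrees of freedom left 0 calls, which met the criterion too. The named genes' amplitudes, however, stayed at a median of 0.937 times those before, while the standard error of the 24 h terms grew 3.12 times. Fitted peaks moved by hours (atp2a1 from 20.58 to 5.06 h), so that fit decides nothing. The explanation is therefore open, and no biological explanation was tested.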

How the results depend on the processing

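No paired analysis was possible because the labels share no replicate numbers between windows. Alternatives with spike-in scaling, without libraries under 100000 reads, without embryos matched to another age, and with genes read in at least 53 embryos were chosen after seeing the data. Where counts moved, the cause was not tested, except that without shallow libraries and with thinning 1 gastrula embryo remained. Named genes kept direction and call in 216 of 320 recomputed values for blastula against gastrula, 274 of 323 for gastrula against segmentation, 319 of 319 for segmentation against pharyngula and 236 of 238 for pharyngula against hatching. Of 224 recomputed list half-rise medians 60 moved by over 120 min, a bound set after the values were seen. With 25% of the maximum 20 of 32 lists did and the median list moved from 1160 to 920 min, and 4 to 9 lists did in the other settings, while the order of lists kept rho of 0.972 to 0.996. At the depth and number of embryos used, simulated 4-fold changes were called in 0%, 3%, 19.4%, 58.2% and 77.6% of cases in the 5 comparisons.

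In the order of the 5 comparisons, calls higher and lower were as follows where they moved by over 1.5 times. RLE: gastrula to segmentation 536 and 1307, segmentation to pharyngula 833 lower, pharyngula to hatching 495 higher. Spike-in scaling: 196 higher (blastula to gastrula), 60 lower (gastrula to segmentation), 2566 and 65 (segmentation to pharyngula). No filter: 6 and 11, 49 lower, 1671 and 924, 4543 and 1381, 2503 and 1754. DESeq2: 12 and 35, 330 and 28, then 319 lower and 217 lower in the last 2. limma-voom: 4 and 3, 292 and 808, 226 lower, 1994 and 354, 706 and 402. All windows in 1 fit: 70 and 29, 477 and 1017, 2918 and 689, 2777 and 654, 735 and 422. For blastula to gastrula, the border 1 embryo earlier gave 73 and 12, 1 later 61 lower, and the pool term 7 and 13. Without shallow libraries the counts were 0 and 0 (blastula to gastrula) and 73 and 39 (gastrula to segmentation), and with thinning 0 and 0, and 65 and 33. Leaving out single embryos gave 0 to 1 lower for cleavage to blastula, and 61 to 112 higher and 31 to 70 lower for blastula to gastrula.

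Genes changing with time numbered 15647 without a filter, 3752 among genes read in at least 53 embryos and 5386 with DESeq2, and 8700 to 13089 otherwise. Rhythm genes numbered 45 with RLE, 70 with spike-in scaling, 3299 without a filter, 2 and 0 with trends of 3 and 6 degrees of freedom, 4 with a period of 20 h, 24 with a depth covariate, 19 without shallow libraries, 53 without libraries under 100000 reads, and 0 in the pharyngula or hatching window alone. Of the 8 rhythm calls of the main fit, 7 were shared with RLE, 4 with spike-in scaling and 4 without shallow libraries. Dissimilarity turned to rho = -0.085 with counts as deposited and -0.106 with Pearson correlation (permutation p = 0.547 and 0.449). The hox rho rose to 0.429 at 25% of the maximum (permutation p = 0.0172). List calls fell from 51 to 9 with an estimated correlation, while 40 of the 51 held with fry and 48 with RLE scaling. With the pool term RPS13 and ANXA1 turned to log2 changes of -0.43 and -1.43 (edgeR adjusted p = 0.91 and 0.871). Without shallow libraries CCNA1 and gdf3 turned to 4.33 and 6.36 (edgeR adjusted p = 0.615), and with thinning to 3.88 and 5.6 (edgeR adjusted p = 0.596).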

Other observations

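Levels here are relative to the unscaled total of gene reads. Reads of genes that rose late were present in several embryos up to 320 min, with the highest values of myhz1.1 in those of 280 and 320 min. Every embryo up to 320 min was in pool A, so this says nothing about the pool. The fast myosin gene myhz1.1 stood at 450.6 CPM in the embryo of 280 min and 553 CPM in that of 320 min, against 8.863 CPM at 240 min and 4.562 CPM at 360 min. The lens gene crygm2d21 stood at 108.5 and 85.42 CPM in the same embryos, against 4.924 CPM at 240 min and no read at 360 min, and serpina1 at 76.94 CPM at 280 min against no read at 240 min. Among earlier embryos myhz1.1 stood at 59.18 CPM at 80 min, 187 CPM at 120 min and 47.59 CPM at 160 min, crygm2d21 at 37.57 CPM at 160 min and serpina1 at 8.024 CPM at 120 min. In the segmentation window, the pool A embryos of 720 and 960 min held them too, with myhz1.1 at 139.8 and 143.7 CPM and crygm2d21 at 44.85 and 43.11 CPM at 720 and 960 min. Embryos of pool B held reads of myhz1.1 as well, with 60.88 CPM at 480 min, 50.79 CPM at 1000 min and 48.17 CPM at 1240 min, while crygm2d21 had no read at 480 and 1000 min and 6.384 CPM at 1240 min. The ribosomal protein share was 4.63% at 280 min, against 1.81% at 200 min and 1.66% at 240 min, so the pattern bears on the blastula values and on the gastrula embryo of 320 min. The embryos of 280 and 320 min include the only gastrula embryo of pool A. The values were noticed after the results were seen, and no explanation was tested, including an exchange of reads between barcodes of a pool.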
